A study of Papio anubis and Macaca fascicularis and Castor canadensis with 48 samples.

How the data were processed

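Bulk RNA sequencing was used to measure gene expression in 48 libraries from the brain, cerebellum, kidney and liver of 8 mammal species. Per the labels' protocols, the organs were frozen on dry ice after removal and RNA was extracted with a column kit (PureLink). The labels describe every animal as a male wild-type adult. They place 39 libraries, those of baboon, beaver and long-tailed macaque, in a collection made at a primate research center. The other 9 libraries, from chipmunk, bear, sugar glider, tube-nosed bat and white-footed mouse, came from an earlier collection. Each species therefore belongs to 1 of 2 collections.

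The authors deposited 1 table of raw read counts, with 1 column per library and 16816 rows, and the table's header names the rows as gene IDs. The counts carry no normalization. STAR, an aligner, and featureCounts, a read counter, are named in the submitters' processing notes. Their versions, the genome builds and the annotation are not given in the sources used here, and neither is the way in which reads of 8 species were assigned to mouse gene IDs. The low counts, those from 1 to 20, were even numbers in 94.3% to 99.4% of cases per library, so a deposited count probably stands for a single read of a pair. All 48 columns matched a sample by name, and 0 columns of per-sample values were left unmatched.

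The rows are mouse Ensembl gene IDs, and the files do not pair them with gene names. No gene is named for that reason, and at most 2 IDs that rose and 2 that fell are printed for a comparison. The 45 gene lists fixed before the data were examined are written as gene symbols, so neither these lists nor the list-based part of the rule for named genes could be tested. Genes that share reads with near-identical copies, overlapping genes and antisense partners could not be recognised without names or coordinates, and whether the counting used strand is not given in the sources used here.

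The 48 libraries were grouped by species and organ into 15 groups. Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, using TMM factors, the filterByExpr filter with its default settings, and the quasi-likelihood F test, which is two-sided. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Organs were compared within baboon (18 libraries fitted) and within long-tailed macaque (17 libraries fitted). Liver and kidney of baboon and macaque were compared between the species, and an interaction term tested whether that difference itself differed between the organs. All 21 livers were fitted in 1 model for the comparisons across species, so that species with 1 library borrowed the spread of the others; such a library is assumed to vary like those of the other species. In these comparisons each species has equal weight on the log scale, whatever its number of libraries. Brain was compared between beaver and baboon with 9 libraries fitted. These 21 comparisons were fixed before the data were examined, and so were their alternatives except those named below as added.

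The named genes followed a rule fixed before the data were examined. Per comparison the rule takes the 5 called genes with the largest and the 5 with the most negative log2 fold change, or 3 and 3 for a species against the other species. A named gene needs a mean of at least 20 CPM and compared sides whose libraries do not overlap. Between species it also needs a count above 0 in every compared library. The interaction has no pair of sides, and there the overlap part of the rule was not applied. The first 2 per direction are printed, or the first for a species against the others. Values are mean CPM ± SD over libraries, where CPM is a count scaled to the total count of its library. For bounds and intervals, 2 deposited counts were taken as 1 read pair. Where every library of a side had 0 counts, the fold is a lower bound against 3 read pairs (6 counts) over that whole group, and the smaller of its values on CPM and on TMM-scaled CPM is given. Where a side had 1 to 3 read pairs, the ratio on TMM-scaled CPM is given, with an exact 95% Poisson interval of the read pairs. Otherwise the fitted log2 fold change is given with a standard error (SE) taken from the F statistic. Binomial intervals of shares in single libraries are exact Clopper-Pearson intervals over read pairs. Intervals and floors cover counting error only, since reads are not independent molecules.

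Groups of genes enriched in an organ were defined after the data had been examined. A gene is organ-enriched here when it was called in baboon with a log2 fold change of at least 2 over both other organs. The groups were then tested in macaque and beaver, whose libraries did not define them, with limma 3.58.1 (camera, preset correlation 0.01, adjusted over 12 tests). In bear and white-footed mouse, with 1 library per organ, a group's median was set against 10000 random lists of the same size matched on mean expression in 20 bins. The comparison of beaver brain with beaver liver was also added after the data had been examined. Library similarity was measured as the Spearman correlation of log2(CPM + 1), and principal components were computed on the same scale. Differences between groups in library measures were tested with two-sided exact permutation tests, adjusted over 32 tests.

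Replicate counts were compared before they were averaged: over 89 pairs of replicates the chi-square per degree of freedom was at least 16.5, so no pair agreed within sampling noise. The labels do not state that replicates come from separate animals, and p-values therefore measure the spread between these libraries, which may be partly technical. The replicate numbers repeat between organs. Same-numbered libraries deviated together from their group means in every pair for baboon kidney and liver (r = 0.100 to 0.328 across genes, 6 pairs), macaque kidney and liver (0.227 to 0.297, 5 pairs) and macaque cerebellum and kidney (0.133 to 0.166, 5 pairs), so that the replicate numbers pair the libraries in these 3 comparisons. This pairing comes from the data, since the labels do not explain the numbers. In the other organ comparisons same-numbered pairs also correlated positively, with r as low as 0.0389. The p-values printed for single genes come from fits without the replicate number as a block, unless the block is named.

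The test was checked on simulated counts with 200 changed genes per comparison. For liver of baboon against macaque it recovered 63% of the 2-fold and 97% of the 4-fold changes. For tube-nosed bat liver, a single library, against the other species it recovered 10% and 59%. Apart from the 200 changed genes, each gene had the same simulated mean level in every group. The changed genes were not drawn from the least counted ones. Far more genes were called in the data, so these rates do not give the sensitivity of the reported comparisons. Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma voom, no low-count filter, a stricter filter (at least 10 counts in every library of a side), a fit of all 48 libraries, leaving out each library in turn, the replicate number as a block, genes counted in every fitted library, and fits within 1 collection. Counts divided by 2, fits without the white-footed mouse liver, and a block of replicate number within species for the interaction were added after the data had been examined. Lifespans are not in the labels, so no value was related to lifespan. Figures were drawn with matplotlib 3.10.9.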

Results

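Gene expression was measured in 48 libraries from 8 mammal species, in a series whose title names longevity across species as its subject. Baboon gave 6 brain, 6 kidney and 6 liver libraries. Long-tailed macaque gave 6 cerebellum, 5 kidney and 6 liver libraries, and beaver gave 2 brain and 2 liver libraries. Chipmunk and sugar glider gave 2 livers each, bear gave 1 kidney and 1 liver, white-footed mouse 1 brain and 1 liver, and tube-nosed bat 1 liver. Groups of 1 library have no replicates. The total count per library ranged from 6.33 M in white-footed mouse brain to 26.8 M in a macaque liver (M, mega). Among the larger groups the mean total was 25.3 M ± 0.784 (SD, n = 6) in baboon liver, 17.3 M ± 1.3 (n = 6) in kidney and 15.6 M ± 0.672 (n = 6) in brain. In macaque it was 24.1 M ± 1.92 (n = 6) in liver, 18.9 M ± 1.40 (n = 5) in kidney and 17.2 M ± 1.98 (n = 6) in cerebellum. Of the 16816 genes, each known here by a mouse Ensembl ID alone, 572 had no count in any library.

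A few genes held much of the counts in primate liver. The 10 most counted genes held 33.1% ± 4.29 of the counts in baboon liver (SD, n = 6), 14.5% ± 1.89 in kidney (n = 6) and 9.17% ± 1.74 in brain (n = 6). In macaque they held 30.8% ± 2.57 in liver (n = 6), 15.9% ± 3.91 in kidney (n = 5) and 7.54% ± 1.28 in cerebellum (n = 6). Among the other livers they held 36.1% ± 0.867 in beaver (n = 2), 18.6% ± 4.06 in chipmunk (n = 2), 16.3% ± 0.619 in sugar glider (n = 2), 42.8% in bear (exact binomial 95% interval 42.73 to 42.80), 45.5% in white-footed mouse (45.43 to 45.50) and 17.4% in tube-nosed bat (17.39 to 17.46). A single gene, ENSMUSG00000029368, held 19.4% ± 4.99 of the counts in baboon liver (n = 6), 17.5% ± 3.14 in macaque liver (n = 6) and 25.7% ± 1.28 in beaver liver (n = 2). It held 29.7% of the bear liver library (29.65 to 29.72) and 18.1% of the white-footed mouse liver library (18.06 to 18.12). The same gene held 0.0857% ± 0.0399 in chipmunk liver (n = 2), 0.00645% ± 0.00660 in sugar glider liver (n = 2) and 0.0286% in tube-nosed bat liver (0.02699 to 0.0302). It was chosen after its values were seen. Liver also had fewer genes at 1 CPM or more: 10914 ± 105 in baboon liver against 12436 ± 130 in kidney and 12782 ± 54.1 in brain (n = 6 each). All 6 livers lay below all 6 kidneys and all 6 brains (exact permutation p = 0.00216, the smallest these arrangements can give, adjusted p = 0.00365 over 32 tests). Liver libraries were also the deepest in both primates, with the same exact permutation p of 0.00216 for total counts in liver against kidney. These permutations exchanged libraries freely and did not keep the pairs of same-numbered kidneys and livers. CPM is scaled to the total count, so the few genes that hold much of the liver counts lower the CPM of all other genes there. The smaller number of genes at 1 CPM or more in liver can come partly from this composition.

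**Figure D1:**
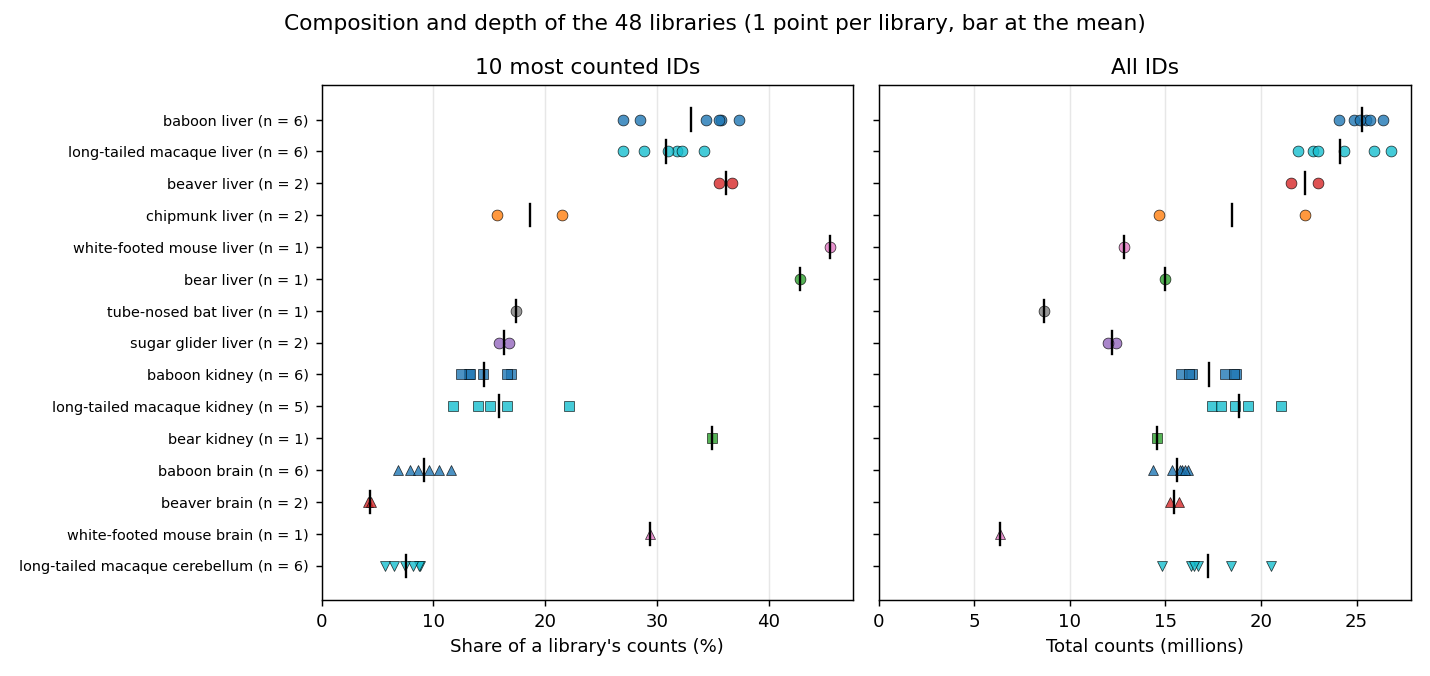
Percent of counts in the 10 most counted genes (left) and total count per library in M (right), with 1 point per library and a bar at the group mean. Baboon liver had 33.1% of counts in the top 10 genes and a mean total of 25.3 M, against 9.17% and 15.6 M in baboon brain.

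In most cases libraries resembled each other first by organ and then by species. The nearest library by Spearman correlation belonged to the same species and organ for 43 of the 43 libraries with a replicate, and to the same organ for 48 of 48. Only the libraries without a replicate can weigh organ against species in this count. With the 8933 genes counted in every library, the nearest library was of the same organ for 46 of 48. Both exceptions lay among the libraries without a replicate, since 43 of 43 again had the same species and organ. With these genes bear kidney correlated at 0.676 with bear liver, against medians of 0.653 with baboon kidney and 0.662 with macaque kidney. White-footed mouse liver correlated at 0.669 with bear kidney, against 0.578 with bear liver, the highest of its medians with other livers. The median correlation across genes was 0.982 between libraries of the same species and organ, 0.857 between species within an organ, and 0.694 between organs within a species. Between libraries that differed in both it was 0.665. By group medians, baboon liver correlated at 0.828 with baboon kidney. This was above its 0.759 to 0.812 with white-footed mouse, sugar glider and bat liver. It was below the 0.853 to 0.948 of baboon liver with bear, beaver, chipmunk and macaque liver. The same order held for macaque liver and kidney. Genes are not independent replicates, and no test was made on these correlations. The first 2 principal components held 51.4% and 18.8% of the variance.

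**Figure D2:**
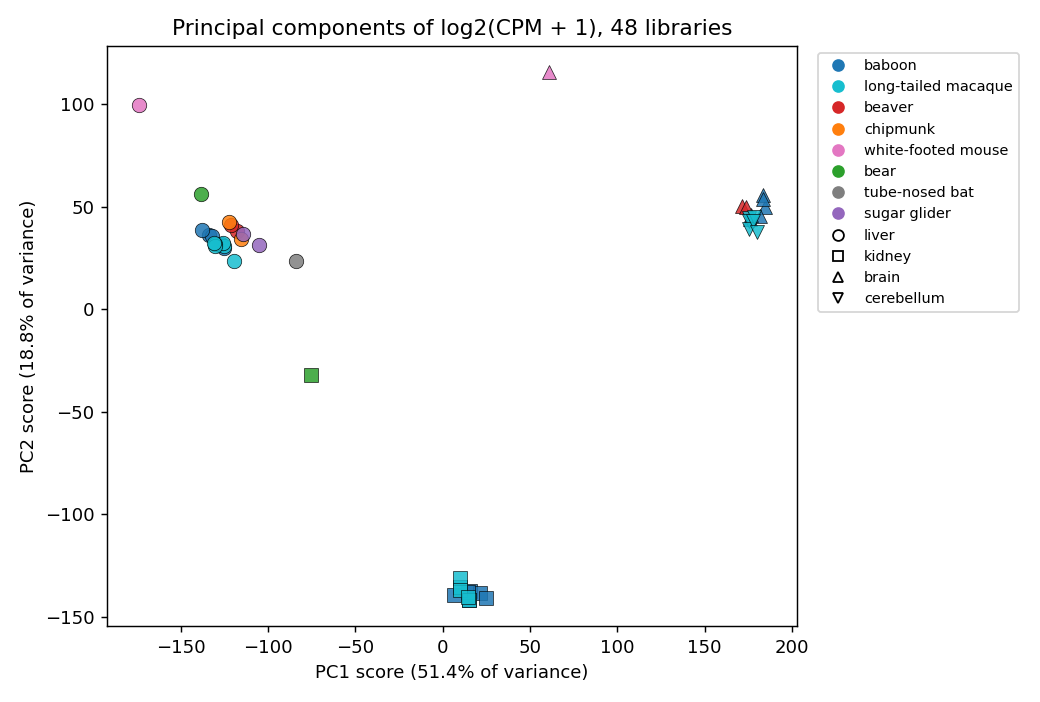
Principal components 1 and 2 of log2(CPM + 1), holding 51.4% and 18.8% of the variance, with 1 point per library, colour for species and marker for organ. Bear kidney (-75.1 and -32.1) and white-footed mouse brain lie away from the other kidneys and brains.

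Within baboon, the organs were compared to find the genes that set brain, kidney and liver apart in a single species. The mean TMM factor was 0.517 in liver, 1.38 in kidney and 1.40 in brain, so fitted fold changes against liver differ from ratios of the CPM given beside them. ENSMUSG00000029054 had 195 CPM ± 44.1 in brain (n = 6) and no count in any of the 6 livers, at least 1828-fold higher in brain (edgeR adjusted p = 4.88e-11). ENSMUSG00000047013 had 162 CPM ± 17.2 in brain and no count in liver, at least 1519-fold higher (edgeR adjusted p = 9.49e-13). ENSMUSG00000027690 had 617 CPM ± 120 in liver and 0.0829 ± 0.128 in brain, a log2 fold change of -14.13 ± 0.60 (SE, edgeR adjusted p = 1.02e-13). ENSMUSG00000016024 had 55 CPM ± 29.9 in liver and no count in brain, at least 858-fold lower in brain (edgeR adjusted p = 1.34e-09). Brain and liver differed in 11443 of 13890 genes tested, 5884 higher and 5559 lower in brain. A fold change of at least 2 was estimated for 8117 of these. Without baboon brain replicate 2 or 6 the log2 fold change of ENSMUSG00000027690 was -14.76.

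Baboon kidney was closer to liver than brain was. ENSMUSG00000032373 had 394 CPM ± 132 in kidney (n = 6) and no count in the 6 livers, at least 3762-fold higher (edgeR adjusted p = 2.19e-10). ENSMUSG00000030160 had 122 CPM ± 54.9 in kidney and no count in liver, at least 1155-fold higher (edgeR adjusted p = 3.03e-10). ENSMUSG00000025991 was lower in kidney by a log2 fold change of -13.55 ± 0.45 (SE, edgeR adjusted p = 5.23e-14), with 2689 CPM ± 516 in liver and 0.592 ± 0.173 in kidney. ENSMUSG00000021999 was lower by -13.23 ± 0.67 (edgeR adjusted p = 6.76e-12), with 857 CPM ± 215 in liver and 0.237 ± 0.328 in kidney. Kidney and liver differed in 9239 of 13890 genes, 4907 higher and 4332 lower in kidney. The median absolute log2 fold change over all tested genes was 0.72 for kidney against liver and 1.34 for brain against liver. Upper-quartile scaling moved the median log2 fold change of all genes from 0.06 to 0.18. Without baboon kidney replicate 6 the log2 fold change of ENSMUSG00000021999 was -14.21.

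Between baboon brain and kidney, 10739 of 13890 genes differed, 5303 higher and 5436 lower in brain. ENSMUSG00000007944 had 152 CPM ± 20.9 in brain (n = 6) and no count in kidney (n = 6), at least 2602-fold higher (edgeR adjusted p = 9.82e-13). ENSMUSG00000041708 had 138 CPM ± 23.1 in brain and no count in kidney, at least 2366-fold higher (edgeR adjusted p = 6.70e-05). ENSMUSG00000050520 had 154 CPM ± 33.7 in kidney and no count in brain, at least 2404-fold lower in brain (edgeR adjusted p = 1.30e-12). ENSMUSG00000023013 had 318 CPM ± 199 in kidney and 2 counts over the 6 brains, a ratio of 14996 with a counting interval of 2692 to 592325 (edgeR adjusted p = 2.59e-12). Both counts lay in baboon brain replicate 6, as from 1 read pair.

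Long-tailed macaque gave cerebellum in place of brain. ENSMUSG00000056222 had 376.6 CPM ± 45.1 in cerebellum (n = 6) and no count in liver (n = 6), at least 3317-fold higher (edgeR adjusted p = 5.31e-14). ENSMUSG00000040972 had 261 CPM ± 43.2 in cerebellum and no count in liver, at least 2300-fold higher (edgeR adjusted p = 2.02e-10). ENSMUSG00000025271 had 70.1 CPM ± 7.86 in liver and no count in cerebellum, at least 1206-fold lower in cerebellum (edgeR adjusted p = 3.79e-11). ENSMUSG00000021620 had 50.4 CPM ± 21 in liver and no count in cerebellum, at least 867-fold lower (edgeR adjusted p = 2.99e-10). Cerebellum and liver differed in 11405 of 13927 genes, 5866 higher and 5539 lower in cerebellum.

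In macaque kidney against liver, 8788 of 13927 genes differed, 4557 higher and 4231 lower in kidney. ENSMUSG00000031766 had 885 CPM ± 137 in kidney (n = 5) and 2 counts over the 6 livers, a ratio of 26985 with a counting interval of 4843 to 1065850 (edgeR adjusted p = 5.11e-14). ENSMUSG00000032327 had 163 CPM ± 84.6 in kidney and no count in liver, at least 1644-fold higher (edgeR adjusted p = 6.61e-08). ENSMUSG00000040017 had 595 CPM ± 252 in liver and 5 counts over the 5 kidneys, a ratio of 22463 with a counting interval of 7686 to 108926 (edgeR adjusted p = 3.12e-12). ENSMUSG00000090306 had 75.4 CPM ± 13.0 in liver and no count in kidney, at least 1185-fold lower (edgeR adjusted p = 3.98e-12). Upper-quartile scaling moved the median log2 fold change of all genes from 0.02 to 0.14. Both liver counts of ENSMUSG00000031766 lay in macaque liver replicate 6, and the kidney counts of ENSMUSG00000040017 in macaque kidney replicate 1 (2 counts) and replicate 2 (3 counts).

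Macaque cerebellum and kidney differed in 10553 of 13927 genes, 5284 higher and 5269 lower in cerebellum. ENSMUSG00000058153 had 206 CPM ± 24.8 in cerebellum (n = 6) and no count in kidney (n = 5), at least 2809-fold higher (edgeR adjusted p = 4.11e-13). ENSMUSG00000061911 had 169 CPM ± 12.1 in cerebellum and no count in kidney, at least 2311-fold higher (edgeR adjusted p = 6.39e-12). ENSMUSG00000020679 had 171 CPM ± 20.4 in kidney and no count in cerebellum, at least 2947-fold lower in cerebellum (edgeR adjusted p = 5.87e-12). ENSMUSG00000029829 had 127 CPM ± 22.4 in kidney and no count in cerebellum, at least 2187-fold lower (edgeR adjusted p = 2.48e-12).

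**Figure D3:**
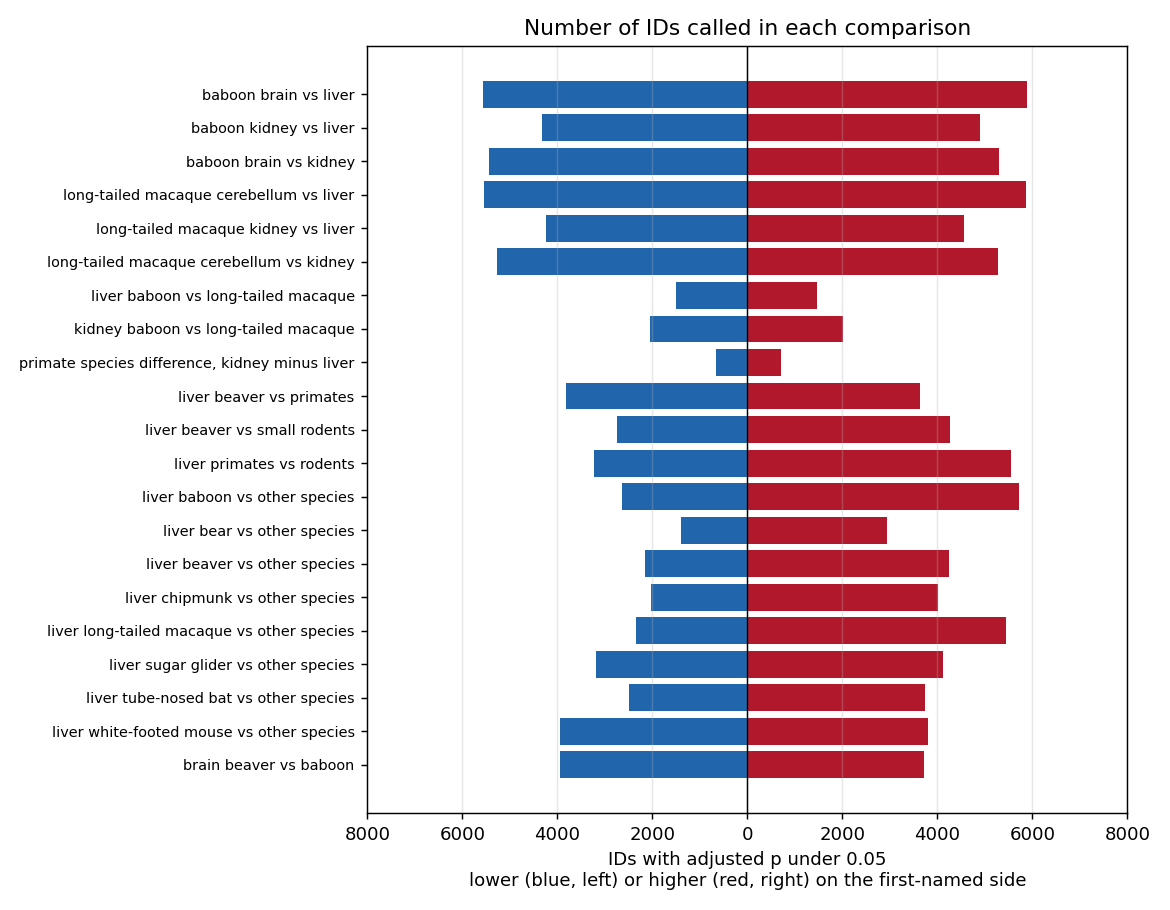
Number of genes past an adjusted p of 0.05 in each of the 21 comparisons, with bars to the left for genes lower and to the right for genes higher on the first-named side. Baboon brain against liver had 11443 such genes and the kidney-minus-liver interaction 1361.

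Groups of organ-enriched genes defined in baboon kept their direction in other species. Of the brain-enriched genes, 1620 of 1738 tested were higher in macaque cerebellum than in liver and 37 were lower, with a median log2 fold change of 4.97, or 4.70 with genes absent from 1 organ placed at their bound. Of the liver-enriched genes, 750 of 788 were lower in macaque kidney than in liver and 4 were higher, with a median of -3.49. Of the kidney-enriched genes, 508 of 548 were higher in macaque kidney than in liver and 3 were lower, with a median of 4.49 (4.44 with such bounds). In each comparison the camera test placed the group apart from the other genes, with adjusted p = 3.86e-61, 1.04e-77 and 3.92e-58, and adjusted p = 9.60e-09, 1.23e-07 and 1.99e-07 with an estimated correlation. Brain-enriched genes were also higher in macaque kidney than in liver, 775 higher and 237 lower of 1738, with a median log2 fold change of 0.73, or 0.55 with such bounds (camera adjusted p = 0.000888). Kidney-enriched genes did not stand apart between macaque cerebellum and liver, with 162 higher, 221 lower and 165 not called of 548 (camera adjusted p = 0.290). Over macaque and beaver, 10 of 12 such tests were called, and the same 10 were called with an estimated correlation (largest adjusted p = 0.0427).

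When the same groups were defined in macaque, the groups of the 2 primates overlapped. The brain-enriched baboon group and the cerebellum-enriched macaque group shared 1293 genes, against 208 for independent lists of those sizes. The kidney-enriched groups shared 413 genes, against 25 for independent lists. The liver-enriched groups shared 604 genes, against 45.3. Across 13560 genes tested in both species, the log2 fold changes of kidney against liver correlated with r = 0.880 (rho = 0.83). Of 7121 genes called in both species for kidney against liver, 6966 had the same direction.

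**Figure D4:**
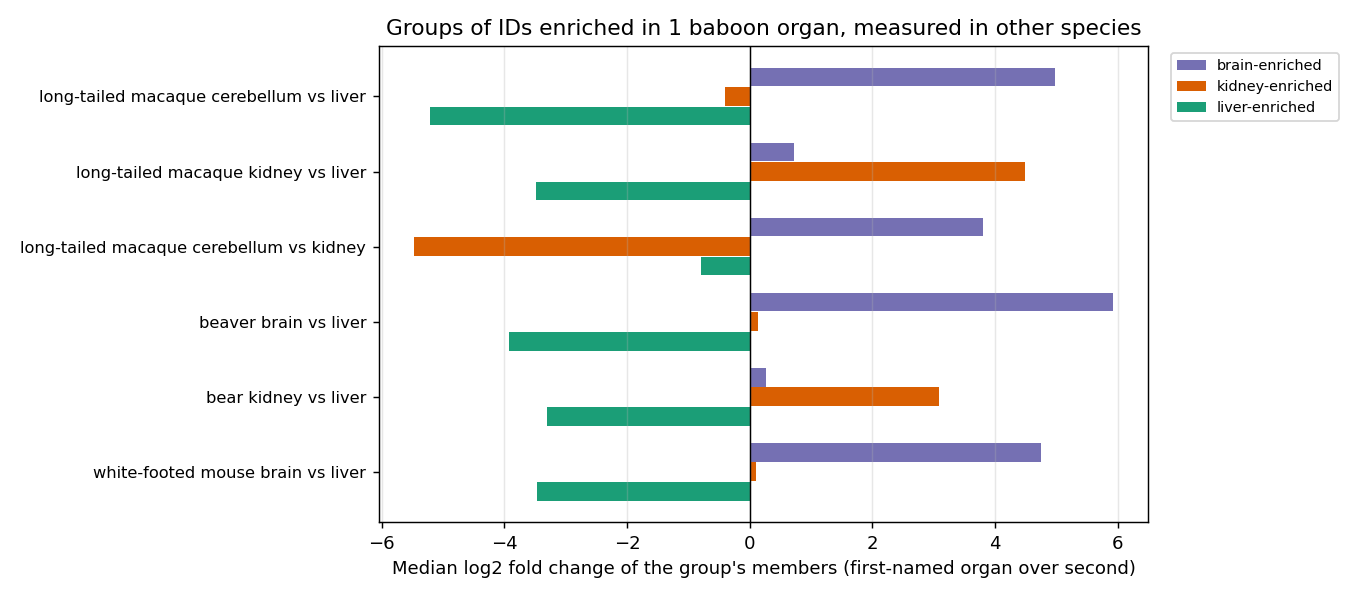
Median log2 fold change of the genes enriched in baboon brain, kidney or liver, with 1 bar per gene group, in macaque, beaver, bear and white-footed mouse, first-named organ over second. The brain-enriched group has a median of 4.97 in macaque cerebellum against liver and 5.93 in beaver brain against liver.

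In beaver, brain and liver could be compared with 2 libraries each. Brain-enriched genes of baboon were higher in beaver brain, 1581 of 1732 tested, and 30 were lower, with a median log2 fold change of 5.93, or 5.22 with genes absent from 1 organ placed at their bound. Liver-enriched genes were lower in beaver brain, 549 of 710 tested, and 36 were higher, with a median of -3.93. Both groups stood apart from the other genes (camera adjusted p = 4.46e-66 and 6.42e-41, and adjusted p = 0.00135 and 0.0152 with an estimated correlation). Kidney-enriched genes split evenly, with 113 higher and 109 lower of 341 (camera adjusted p = 0.246). In all, 8576 of 13309 genes differed between beaver brain and liver, 4681 higher and 3895 lower in brain. The count was 5519 without beaver brain replicate 1 and 5522 without replicate 2, which leaves 1 brain library. Of 7373 genes called for brain against liver in both beaver and baboon, 6718 had the same direction, against 3463 for independent lists (r = 0.821 across 12869 genes).

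Bear kidney and liver, and white-footed mouse brain and liver, had 1 library each, so these differences have no replicate check. In bear, 407 of the 461 kidney-enriched genes measured had more CPM in kidney than in liver, with a median log2 ratio of 3.09, above all 10000 random lists (-0.52 to 0.33). Of the liver-enriched genes, 630 of 724 had less in bear kidney, with a median of -3.31. Brain-enriched genes went both ways in bear, 559 with more in kidney and 471 with less, with a median of 0.27, above all 10000 random lists (-0.48 to 0.12). In white-footed mouse, 1550 of 1607 brain-enriched genes had more in brain, with a median of 4.75, above all 10000 random lists (0.53 to 1.23). Of the liver-enriched genes, 583 of 662 had less in mouse brain, with a median of -3.46. Kidney-enriched genes split evenly in mouse, 130 with more in brain and 129 with less, with a median of 0.11, below all 10000 random lists (0.19 to 2.43).

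The liver of baboon and macaque was compared to find differences between related primates of the same collection. ENSMUSG00000032081 had 1486 CPM ± 405 in baboon liver and 0.397 ± 0.193 in macaque liver (n = 6 each), a log2 fold change of 11.97 ± 0.41 (SE, edgeR adjusted p = 2.76e-10). ENSMUSG00000007891 had 728 CPM ± 193 in baboon and 3.75 ± 1.36 in macaque, a log2 fold change of 7.71 ± 0.29 (edgeR adjusted p = 4.88e-10). ENSMUSG00000057322 was lower in baboon by -7.42 ± 0.21 (edgeR adjusted p = 1.43e-10), with 0.777 CPM ± 0.256 against 145 ± 16.1. ENSMUSG00000042554 was lower by -5.96 ± 0.43 (edgeR adjusted p = 4.84e-07), with 7.11 CPM ± 4.14 against 490 ± 121. Of 11948 genes tested, 2961 differed, 1468 higher and 1493 lower in baboon, with a median absolute log2 fold change of 0.32 over all genes. A fit of all 48 libraries together tested 15456 genes and called 4969. How reads of each species were assigned to mouse gene IDs is unknown, so a fold change between species can hold a difference in gene models as well as in expression, here and in each comparison of species that follows.

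The kidneys of the 2 primates differed in 4046 of 13082 genes, 2002 higher and 2044 lower in baboon. ENSMUSG00000061099 had 793 CPM ± 119 in baboon kidney (n = 6) and 4.71 ± 0.880 in macaque kidney (n = 5), a log2 fold change of 7.33 ± 0.20 (SE, edgeR adjusted p = 8.20e-11). ENSMUSG00000007891, also higher in baboon liver, had 912 CPM ± 177 in baboon kidney and 7.42 ± 3.35 in macaque, a log2 fold change of 6.88 ± 0.32 (edgeR adjusted p = 1.37e-08). ENSMUSG00000057322, also lower in baboon liver, was lower in baboon kidney by -7.32 ± 0.16 (edgeR adjusted p = 3.60e-11), with 1.57 CPM ± 0.455 against 240 ± 8.44. ENSMUSG00000042678 was lower by -7.22 ± 0.32 (edgeR adjusted p = 9.78e-09), with 0.435 CPM ± 0.262 against 63.8 ± 20.1.

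Genes that differed between the species in both liver and kidney mostly had the same direction. Of 11639 genes tested in both organs, 2863 were called in liver, 3504 in kidney and 1424 in both, and 1317 of the 1424 (92.5%) had the same direction. The genes higher in baboon in both organs numbered 628, against 206 for independent lists, and those lower in both numbered 689, against 226. The log2 fold changes of the organs correlated with r = 0.618 and rho = 0.450 across genes. Liver and kidney libraries of the same number deviated together, so the organs are not independent. Over 10 fits of 3 libraries per group r was 0.527 to 0.592 with different numbers in liver and kidney. It was 0.569 to 0.5996 with the same numbers. The ranges of rho did not overlap, at 0.328 to 0.401 with different numbers and 0.408 to 0.438 with the same.

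**Figure D5:**
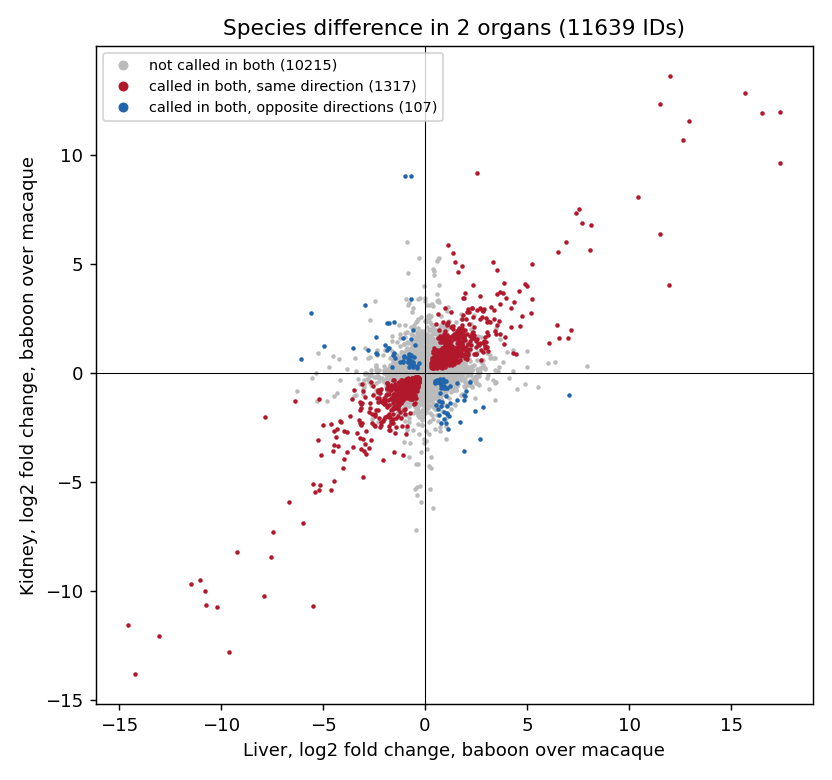
Log2 fold change of baboon over macaque in kidney against that in liver, with 1 point per gene over 11639 genes and colour for the genes called in both organs. Of 1424 genes called in both, 1317 have the same direction.

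The species difference itself differed between kidney and liver in 1361 of 13600 genes, by the interaction term. With same-numbered kidney and liver libraries as a block within each species the count was 1391, and 1078 genes were called in both fits. ENSMUSG00000009246 had 15.3 CPM ± 8.97 in baboon kidney (n = 6) and 1.44 ± 0.586 in macaque kidney (n = 5), but 12.1 ± 19.1 in baboon liver and 69.3 ± 18.4 in macaque liver (n = 6 each). Its interaction was 5.76 ± 1.14 on the log2 scale (SE, edgeR adjusted p = 0.00182), 7.07 without baboon liver replicate 4 and 7.12 with the block. ENSMUSG00000032348 had 2.88 CPM ± 1.35 in baboon kidney and 169 ± 214 in macaque kidney, with 2678 ± 1004 in baboon liver and 3361 ± 1287 in macaque liver. Its interaction was -5.74 ± 0.88 (edgeR adjusted p = 0.000149), -4.55 without macaque kidney replicate 3 and -4.92 with the block. ENSMUSG00000055653 had 221 CPM ± 50.7 in baboon kidney and 154 ± 40.6 in macaque kidney, with 55.2 ± 62.0 in baboon liver and 0.865 ± 0.386 in macaque liver, an interaction of -5.54 ± 0.88 (edgeR adjusted p = 0.000222). It was -4.86 without baboon liver replicate 5 and -4.68 with the block, and limma voom gave an adjusted p of 0.0649 (4.45e-10 to 0.0649 over 33 alternatives).

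ENSMUSG00000098411 had the largest positive interaction among the named genes, 6.09 ± 1.53 (SE, edgeR adjusted p = 0.0119), and rested on few libraries. Its level was 254 CPM ± 358 in baboon kidney (n = 6), 28.2 ± 25.9 in macaque kidney (n = 5), 7.22 ± 7.37 in baboon liver (n = 6) and 59.2 ± 101 in macaque liver (n = 6). The interaction was 4.97 without baboon kidney replicate 5, 4.37 without macaque liver replicate 1, 6.77 without baboon liver replicate 4 and 6.78 without macaque kidney replicate 1. With the block it was 4.605 (edgeR adjusted p = 0.0488). With limma voom the adjusted p was 0.0988 (0.000252 to 0.0988 over 33 alternatives). Of the 1361 genes, 708 had a more positive baboon-minus-macaque difference in kidney and 653 in liver. In both organs 107 of them were called in opposite directions and 123 in the same direction, while 365 were called in kidney and tested but not called in liver, and 507 the reverse. A further 101 were called in kidney and not tested in liver, and 25 were called in liver and not tested in kidney.

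Genes enriched in the liver of both primates, 604 in all, were followed through the livers of the 8 species. They held 60.3% of the counts in baboon, 57.5% in macaque, 56.6% in beaver and 59.99% in bear liver. Their share was 47.6% in white-footed mouse, 39.6% in chipmunk, 28.6% in sugar glider and 25.9% in tube-nosed bat liver. The size of this contrast rests partly on ENSMUSG00000029368, a member of the group. Without it the share was 50.7% in baboon, 48.4% in macaque, 43.1% in bear, 41.7% in beaver, 39.55% in chipmunk, 36.0% in white-footed mouse, 28.6% in sugar glider and 25.9% in bat. A mean of more than 10 CPM was reached by 494 of the 604 genes in baboon, 491 in macaque, 417 in chipmunk, 409 in bat, 405 in bear, 401 in beaver, 371 in sugar glider and 310 in white-footed mouse. The group was chosen in primates, so its level there is not independent of the choice. No count in any liver was found for 87 of the genes in sugar glider, 54 in white-footed mouse, 43 in bear, 42 in bat, 41 in beaver and 27 in chipmunk. Some genes abundant in other livers were nearly absent in sugar glider (10 of 77), in bat (4 of 76) and also in beaver (9 of 76), whose share was high. How many of them belong to this group was not counted. The shares can therefore hold a difference in the assignment of reads as well as in expression.

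Beaver liver was set against the primate livers of the same collection. ENSMUSG00000004032 had 1320 CPM ± 428 in beaver (n = 2) and 2.35 ± 1.16 in the primates (n = 12), a log2 fold change of 9.11 ± 0.33 (SE, edgeR adjusted p = 2.06e-12). ENSMUSG00000049685 had 409 CPM ± 34.6 against 1.68 ± 1.37, a log2 fold change of 8.08 ± 0.40 (edgeR adjusted p = 6.30e-11). ENSMUSG00000064363 was lower in beaver by -14.48 ± 0.70 (edgeR adjusted p = 4.98e-11), with 0.308 CPM ± 0.304 against 9915 ± 8164. ENSMUSG00000064367 was lower by -14.26 ± 0.57 (edgeR adjusted p = 4.59e-12), with 0.267 CPM ± 0.115 against 5234 ± 1728. Of 14371 genes, 7450 differed, 3638 higher and 3812 lower in beaver. Without the livers of the other collection 7267 of 13125 genes differed, and 7094 of these were called in both fits. The log2 fold change of ENSMUSG00000064363 was -13.74 without beaver liver replicate 1 and -16.19 without replicate 2.

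Within rodents, beaver liver was compared with chipmunk and white-footed mouse liver. ENSMUSG00000022613 had 977 CPM ± 130 in beaver (n = 2) and 1.56 ± 1.40 in the small rodents (n = 3), a log2 fold change of 8.88 ± 1.41 (SE, edgeR adjusted p = 6.43e-05), and 10.71 without chipmunk liver replicate 1. ENSMUSG00000027199 had 1270 CPM ± 145 against 1.97 ± 1.0, a log2 fold change of 8.82 ± 0.78 (edgeR adjusted p = 1.91e-07). ENSMUSG00000064358 was lower in beaver by -15.83 ± 1.14 (edgeR adjusted p = 2.44e-08), with 0.395 CPM ± 0.427 against 16448 ± 9234. ENSMUSG00000064363, also lower than in primates, was lower by -15.48 ± 0.73 (edgeR adjusted p = 1.73e-10). Of 14371 genes, 7018 differed, 4268 higher and 2750 lower in beaver. The genes higher in beaver made up 60.8% of the calls, and 50.6% of 5839 calls without the white-footed mouse library, of which 3851 were called in both fits. The median log2 fold change of all genes was 0.23, and 0 without the white-footed mouse library, 0.03 with DESeq2, 0.08 with RLE factors and 0.10 with limma voom. Beaver and the small rodents belong to different collections, so species and collection cannot be told apart here. Without beaver liver replicate 1 and 2 the log2 fold change of ENSMUSG00000064358 was -15.03 and -17.90, and that of ENSMUSG00000064363 was -14.73 and -17.19.

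Primate livers were then compared with the livers of the 3 rodents. With so few species, SE and p measure the spread between libraries within species, not between species. This holds in every liver comparison that pools species. ENSMUSG00000026303 had 37.1 CPM ± 49.0 in primates (n = 12) and 0.185 ± 0.0547 in rodents (n = 5), a log2 fold change of 7.36 ± 2.01 (SE, edgeR adjusted p = 0.00459). Its log2 fold change was 6.69 without baboon liver replicate 6, and limma voom gave an adjusted p of 0.129 (2.36e-09 to 0.129 over 26 alternatives). ENSMUSG00000012819 had 96.0 CPM ± 39.6 against 2.55 ± 2.55, a log2 fold change of 6.03 ± 0.45 (edgeR adjusted p = 6.67e-09). ENSMUSG00000016255 was lower in primates by -7.99 ± 0.22 (edgeR adjusted p = 4.83e-14), with 0.658 CPM ± 0.442 against 133 ± 104. ENSMUSG00000022820 was lower by -7.16 ± 0.17 (edgeR adjusted p = 1.12e-14), with 1.25 CPM ± 1.08 against 99.3 ± 84.0. Of 14371 genes, 8782 differed, 5551 higher and 3231 lower in primates, or 63.2% higher. Within the collection of the primates, where beaver is the sole rodent, 7267 genes differed, 3833 higher and 3434 lower, or 52.7% higher, and 5308 of them were also called in the full comparison. Without the white-footed mouse library 8178 genes differed, 54.3% of them higher, and 6221 were called in both fits. The median log2 fold change of all genes was 0.37, and 0.11 without that library, 0.22 with DESeq2 and 0.18 with limma voom.

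Each species' liver was also compared with the mean of the other 7 species. In baboon, 8369 of 14371 genes differed, 5721 higher and 2648 lower (68.4% higher). ENSMUSG00000030882 had 218 CPM ± 129 in baboon (n = 6) and 8.41 ± 12.1 in the others (n = 15), a log2 fold change of 5.63 ± 0.71 (SE, edgeR adjusted p = 3.09e-06). ENSMUSG00000022820 was lower by -7.43 ± 0.23 (edgeR adjusted p = 2.02e-13), with 0.277 CPM ± 0.0830 against 59.4 ± 68.4. With genes counted in every liver, 3420 of 6030 called genes were higher (56.7%), and within the collection 3313 of 5969 (55.5%). In macaque, 7797 genes differed, 5448 higher and 2349 lower (69.9% higher). ENSMUSG00000064246 had 798 CPM ± 374 in macaque (n = 6) and 9.78 ± 12.4 in the others (n = 15), a log2 fold change of 8.33 ± 0.71 (edgeR adjusted p = 4.12e-08). ENSMUSG00000061099 was lower by -9.20 ± 0.28 (edgeR adjusted p = 5.70e-13), with 2.00 CPM ± 0.770 against 1045 ± 915. With genes counted in every liver, 3251 of 5614 called genes were higher (57.9%), with limma voom 4588 of 7894 (58.1%), and within the collection 3247 of 5567 (58.3%). The median log2 fold change of all genes was 0.32 in baboon, 0.21 with DESeq2, 0.15 with limma voom and 0.20 without the white-footed mouse library. In macaque it was 0.30, 0.18 with DESeq2, 0.12 with limma voom and 0.18 without that library.

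Among rodents, beaver liver differed from the mean of the other species in 6387 of 14371 genes, 4239 higher and 2148 lower (66.4% higher). ENSMUSG00000004032 had 1320 CPM ± 428 in beaver (n = 2) and 10.6 ± 20.3 in the others (n = 19), a log2 fold change of 6.97 ± 0.36 (SE, edgeR adjusted p = 2.30e-10). ENSMUSG00000064363 was lower by -14.28 ± 0.70 (edgeR adjusted p = 1.06e-10), and by -13.53 and -15.99 without beaver liver replicate 1 and 2. Of the calls in beaver, 54.2% of 6828 were higher with DESeq2, 55.5% of 4907 with genes counted in every liver, and 47.3% of 7267 within the collection. In chipmunk, 6057 genes differed, 4018 higher and 2039 lower (66.3% higher), and 5943 within the earlier collection, 3927 higher. ENSMUSG00000037852 had 978 CPM ± 268 in chipmunk (n = 2) and 10.1 ± 6.26 in the others (n = 19), a log2 fold change of 7.18 ± 0.24 (edgeR adjusted p = 3.78e-12). ENSMUSG00000026390 was lower by -7.73 ± 0.67 (edgeR adjusted p = 1.02e-07), with 1.06 CPM ± 0.618 against 170 ± 170. In chipmunk 53.6% of 6537 calls were higher with DESeq2 and 54.2% of 4843 with genes counted in every liver. The median log2 fold change of all genes was 0.15 in beaver, 0.03 with DESeq2 and 0.05 with limma voom, and 0.13 in chipmunk, -0.01 with DESeq2 and 0.00 with limma voom.

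The white-footed mouse liver, a single library, differed most from the rest. Its median absolute log2 fold change over all genes was 1.96, against 0.76 to 1.25 in the other 7 comparisons of this kind. On the third principal component (6.0% of the variance) it scored -132, near white-footed mouse brain (-134) and bear kidney (-137), also single libraries of the earlier collection. All other libraries lay between -41.7 and 49.5. A trait of the species' liver cannot be told apart from a feature shared by the named libraries. White-footed mouse liver differed in 7751 of 14371 genes, 3796 higher and 3955 lower, and in 7127 within the earlier collection, 3549 higher. ENSMUSG00000029269 had 458 CPM in this library and 12.3 ± 22.9 in the others (n = 20), a log2 fold change of 7.59 ± 0.57 (SE, edgeR adjusted p = 5.58e-09). ENSMUSG00000029369 had 2 counts, against 976 CPM ± 656 in the others, a ratio of 1457 with equal weight per species and a counting interval of 262 to 57552 (edgeR adjusted p = 9.13e-07). The median log2 fold change of all genes was -0.65, and -0.17 with DESeq2, -0.37 with RLE factors and -0.22 with limma voom, so the levels of single genes in this library stand relative to that shift.

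In sugar glider liver, 7298 of 14371 genes differed from the other species, 4120 higher and 3178 lower, and 6910 within the earlier collection, 3935 higher. ENSMUSG00000074785 had 1073 CPM ± 437 in sugar glider (n = 2) and 9.67 ± 7.66 in the others (n = 19), a log2 fold change of 7.93 ± 0.54 (SE, edgeR adjusted p = 2.11e-09). ENSMUSG00000002985 was lower by -11.78 ± 0.63 (edgeR adjusted p = 1.32e-10), with 2.92 CPM ± 2.71 against 8127 ± 11545. It was lower by -13.28 without sugar glider liver replicate 1 and by -11.06 without replicate 2. In tube-nosed bat liver, 6236 genes differed, 3749 higher and 2487 lower, and 5520 within the earlier collection, 3355 higher. ENSMUSG00000048489 had 833 CPM in the bat library and 12.1 ± 16.9 in the others (n = 20), a log2 fold change of 6.34 ± 0.85 (edgeR adjusted p = 1.18e-05). ENSMUSG00000032083 had 11.3 CPM against 8410 ± 5864, a log2 fold change of -10.19 ± 0.67 (edgeR adjusted p = 5.20e-09).

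Bear liver, also a single library, had the fewest calls, 4335 of 14371 genes, 2935 higher and 1400 lower (67.7% higher). Within the earlier collection it differed in 4256 genes, 2896 higher, and with genes counted in every liver 57.1% of 3091 calls were higher. The median log2 fold change of all genes was 0.08, and -0.03 without the white-footed mouse library. ENSMUSG00000032496 had 2571 CPM in the bear library and 46.2 ± 133 in the others (n = 20), a log2 fold change of 7.59 ± 0.72 (SE, edgeR adjusted p = 5.97e-07). ENSMUSG00000060560 had 2 counts in bear liver, against 328 CPM ± 397 in the others, a ratio of 912 with equal weight per species and a counting interval of 164 to 36021 (edgeR adjusted p = 1.68e-10).

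Beaver brain was compared with baboon brain, from the same collection. ENSMUSG00000055194 had 3141 CPM ± 35.7 in beaver (n = 2) and 0.387 ± 0.124 in baboon (n = 6), a log2 fold change of 12.85 ± 0.18 (SE, edgeR adjusted p = 1.50e-10). ENSMUSG00000016255, also higher in rodent than in primate liver, had 3296 CPM ± 202 against 2.49 ± 0.509, a log2 fold change of 10.25 ± 0.18 (edgeR adjusted p = 7.25e-10). ENSMUSG00000064367, also lower in beaver liver than in primate liver, was lower in beaver brain by -12.11 ± 1.11 (edgeR adjusted p = 2.38e-05), with 3.58 CPM ± 4.32 against 14689 ± 4898. ENSMUSG00000064345 was lower by -11.46 ± 0.92 (edgeR adjusted p = 1.10e-05), with 4.15 CPM ± 4.76 against 10939 ± 2421. Of 14484 genes, 7674 differed, 3719 higher and 3955 lower in beaver. Of 4119 genes called both here and for beaver liver against primates, 3187 (77.4%) had the same direction, with r = 0.490 and rho = 0.364 across 13700 genes. Independent lists would share 921 genes higher and 992 lower, and 1552 and 1635 were shared. Without beaver brain replicate 1 and 2 the log2 fold change of ENSMUSG00000064367 was -14.88 and -11.22, and that of ENSMUSG00000064345 was -13.88 and -10.61.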

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

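All tests of the 3 patterns below, and the splits of the comparisons between species, were chosen after the results were seen; the splits of the 6 organ comparisons were not.

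Several genes that were abundant in most livers were nearly absent in single species, at under a hundredth of the median level of the other species. Among genes over 1000 CPM in at least 4 other species, this held for 10 of 77 in sugar glider and 9 of 76 in beaver. It held for 5 of 74 in macaque, 4 of 76 in tube-nosed bat and 2 of 71 in chipmunk. In baboon it held for 2 of 73, of which 0 were abundant in macaque kidney. In bear and white-footed mouse it held for 0. At under a thousandth, 0 remained in chipmunk and 2 in bat. Depth is argued against, since at the median level of the other species at least 13243 counts were due for each of these genes. In beaver, of the 5 that were abundant in baboon brain, 100% were also lost in beaver brain, against 0 of 67 other abundant genes. In macaque the figure was also 100%, but from 1 gene in kidney and 2 in cerebellum, and for the 16 losses in the 3 species with liver alone no second organ exists. Reads that are not assigned to these IDs and genes without expression in either organ both predict a loss in both organs. Counts without gene names therefore cannot tell them apart in these 5 species. What the genes encode, which could bear on this, was not available here. By another rule, genes were missing in a species with at least 10 CPM in every other species' liver and under 0.1 CPM in its own. Of those high in a second organ of other species, 0 of 1 were missing in beaver brain and 0 of 6 in mouse brain. In baboon kidney 0 of 2 were missing, and in bear kidney 1 of 2. By that rule a loss in liver did not always recur in a second organ.

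Of 1424 genes that differed between baboon and macaque in both liver and kidney, 1317 had the same direction, while 2863 were called in liver and 3504 in kidney among the genes tested in both. A pattern made by the same animals giving both organs is argued against as the whole cause. Over 10 fits with different replicate numbers in liver and kidney the lowest r across genes was still 0.527. With the same numbers r was 0.569 to 0.5996. By rank the values were lower with different numbers, rho = 0.328 to 0.401 against 0.408 to 0.438, so a partial role stays open. Each fit with different numbers used liver number 4 and none with the same numbers did, so the fits also differ in libraries. For the 1317 genes with the same direction, an assignment of reads to gene IDs that favours a species alike in every organ and a difference in expression cannot be told apart, because both predict the same direction. The 107 genes called in opposite directions lack the shared direction by choice, so they decide nothing about it. A biological difference between the species stays open and was not tested.

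In 5 comparisons of a liver with the mean of the other species (baboon, bear, beaver, chipmunk and macaque), 66.3% to 69.9% of the called genes were higher. With genes counted in every liver the highest of the 5 shares was 57.9%, but that filter takes out genes by the zeros that can make a gene higher in the named species, so the part of genes with a count of 0 stays open. Without the white-footed mouse liver the 5 shares were 62.7% to 65.2%. Within 1 collection the share was 47.3% in beaver, 55.5% in baboon and 58.3% in macaque, against 66.1% in chipmunk and 68.0% in bear, so the excess was smaller or absent in 3 of the 5; these fits also change which species a liver is compared with, so collection and species cannot be told apart. Scaling as the whole cause is argued against, since with RLE or upper-quartile factors the lowest share was 61.5%. DESeq2, which changes the scaling and the test together, gave 54.2% in beaver and 53.6% in chipmunk. A biological cause was not tested.

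The difference between baboon and macaque differed between kidney and liver in 1361 genes by the interaction term. Bear kidney, which enters no tested comparison, carried a kidney signal, with a median log2 ratio of 3.09 for kidney-enriched genes against bear liver.

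Of 95 sets of values, each a named gene or a library measure in a group of 5 or 6 libraries, 12 held a library far from the rest, against 4.75 at a rate of 5%; the sets share libraries and are not independent. In macaque liver replicate 2, ENSMUSG00000029368 held 11.5% of counts, against 17.3% to 20.1% in the others. ENSMUSG00000029054 had 111 CPM in baboon brain replicate 2, against 189 to 234. ENSMUSG00000030160 had 227 CPM in baboon kidney replicate 5, against 74.9 to 123. ENSMUSG00000023013 had 705 CPM in baboon kidney replicate 3, against 144 to 315. ENSMUSG00000061911 had 145 CPM in macaque cerebellum replicate 1, against 170 to 178. ENSMUSG00000098411 had 947 CPM in baboon kidney replicate 5, against 10.2 to 338, 264 CPM in macaque liver replicate 1, against 4.93 to 39.96, and 21.9 CPM in baboon liver replicate 4, against 1.58 to 6.11. ENSMUSG00000009246 had 49.0 CPM in the same baboon liver, against 0.628 to 16.2. ENSMUSG00000032348 had 538 CPM in macaque kidney replicate 3, against 13.7 to 147. ENSMUSG00000016255 had 1.73 CPM in macaque liver replicate 5, against 0.657 to 1.06, and ENSMUSG00000022820 had 1.27 CPM in macaque liver replicate 1, against 2.19 to 2.70.

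The counts of called genes were set against other allotments of single libraries where each compared side held at least 3 libraries. The liver fits of 8 species also hold species with fewer. Libraries already grouped by species and organ, so splits that mix them raise the spread within a side and were likely to call fewer genes. The splits therefore show only that the real grouping called more genes than mixed ones. In each of 12 comparisons, 1 of 100 splits, the real grouping, gave as many genes. Real values and the highest other split were 11443 and 4943 for baboon brain against liver, 9239 and 2624 for kidney against liver, and 10739 and 4265 for brain against kidney. In macaque they were 11405 and 4083 for cerebellum against liver, 8788 and 6904 for kidney against liver, and 10553 and 8314 for cerebellum against kidney. Between baboon and macaque they were 2961 and 5 in liver, 4046 and 2004 in kidney, and 1361 and 1 for the interaction with species exchanged within each organ, or 86 over 100 splits that exchange species for whole same-numbered pairs. With livers assigned at random to the 8 species they were 8782 and 2754 for primates against rodents. They were 8369 and 2471 for baboon against the others, and 7797 and 728 for macaque against the others. These liver splits mix libraries of different species. They cannot show whether another grouping of whole species would call as many genes. Among the 32 splits that part every same-numbered pair, the highest other was 2839 for baboon kidney and liver, 6822 for macaque kidney and liver and 8200 for macaque cerebellum and kidney; these splits exchange the organs of some numbers.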

How the results depend on the processing

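Counts divided by 2, fits without the white-footed mouse liver, the block for the interaction, all alternatives for organ-enriched genes, beaver brain against liver and lost genes, and the thresholds of 5 CPM and a thousandth were chosen after the data had been seen; the other alternatives were planned. Over 22 comparisons, 520 of 523 alternatives gave a count of called genes within 1.5 times the reported one and 3 did not. The count for liver of baboon against macaque was 4969 with all 48 libraries fitted, against 2961. That fit tested more genes, 15456 against 11948. For kidney the same fit called fewer genes, 3488 against 4046, so testing more genes need not raise the count. The cause was not tested further. The count for beaver brain against liver ranged from 5519 to 8529 with a library left out, against 8576, and the lower values had 1 brain library. The first 2 named genes per direction of each comparison, 84 results that are not all printed, kept their direction in all 2049 alternatives. Of these alternatives, 3 ended a call, all with limma voom, for ENSMUSG00000055653, ENSMUSG00000098411 and ENSMUSG00000026303. The named genes were picked for large fold changes and, outside the interaction, for sides that do not overlap. A change of direction was therefore hardly possible, and the kept directions say little about other genes. With a log2 fold change of at least 3 as the threshold, liver-enriched genes between macaque cerebellum and kidney had an adjusted p of 0.113 with an estimated correlation, and with at least 1 kidney-enriched genes in beaver had 0.0424. In the comparison of beaver with small rodents no fit within a collection was possible.

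For the pairing, the replicate block changed no count of calls by over 1.5 times: 9345 for baboon kidney against liver, 8864 for macaque kidney against liver, 10704 for macaque cerebellum against kidney and 1391 for the interaction, with 1 block per number and species. The genes printed for these organ comparisons stayed called with the block, but with larger adjusted p. The largest was 3.07e-06 for ENSMUSG00000032327 in macaque kidney against liver, against 6.61e-08 without the block (edgeR). In the other organ comparisons not every same-numbered pair correlated above 0.1, the cut-off used here. It was passed by 3 of 6 for baboon brain and kidney, 0 of 6 for brain and liver and 1 of 6 for macaque cerebellum and liver. Libraries correlated best with their own number in 5 of 6, 6 of 6 and 6 of 6 cases. All 36 same-numbered pairs correlated positively (lowest r = 0.0389), so the numbers go with a pairing there too, at mostly lower r. In beaver only 2 pairs exist (r = 0.104). The replicate block gave 10897, 11537 and 11527 in the 3 primate comparisons, and 8121 in beaver.

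In simulated counts the test recovered 29% of 2-fold changes for beaver liver against primates and 34% for the interaction, against 82% for baboon kidney against liver.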

Other observations

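The livers of the 8 species differed in how close they stood to each other. The median correlation across genes was 0.948 between baboon and macaque liver and 0.958 between their kidneys. Baboon brain and macaque cerebellum, different parts of the brain, correlated at 0.915, and baboon brain and beaver brain at 0.907. Chipmunk liver correlated at 0.868 with beaver liver, 0.865 with macaque liver, 0.862 with baboon liver and 0.857 with bear liver. White-footed mouse liver correlated at 0.730 with sugar glider liver and 0.778 with chipmunk liver, the lowest and highest of its values with other livers. This library had 8480 genes at 1 CPM or more, the fewest of the 48 libraries, and 45.5% of its counts (exact binomial 95% interval 45.43 to 45.50) lay in its 10 most counted genes.

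The brain of white-footed mouse had 29.4% of its counts in 10 genes (29.35 to 29.45), against 9.17% ± 1.74 in baboon brain (n = 6) and 4.30% ± 0.175 in beaver brain (n = 2). Bear kidney had 34.9% in 10 genes (34.89 to 34.96), against 14.5% ± 1.89 in baboon kidney (n = 6).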
